A study of Homo sapiens with 10 samples.

How the data were processed

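The data are 10 arrays of total RNA from primary human aortic smooth muscle cells, 3 from serum-fed cells (control), 4 after 48 h and 3 after 72 h in serum-free medium. Per the labels' protocols, the RNA integrity numbers ranged from 8.5 to 10, and 100 ng of RNA from each sample was treated with phosphatase and then ligated to a nucleotide carrying Cy3. The labels state that several arrays were left out after quality control, which leaves these 10. Groups and replicate numbers were taken from the sample titles and descriptions.

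Per the file headers, the arrays were read with Agilent Feature Extraction 10.1.1.1, and the submitters' processing notes name the same program. The deposited scanner files hold spot intensity on a linear scale: the processed intensity, from which Feature Extraction had subtracted the background, is negative for some spots and is not scaled between arrays. The deposited value table of the series holds intensity as well. Its values equalled the total gene signal of the scanner files in 100% of cases within 1e-04, so its scale, centring and direction are known, and the alternatives built on these values coincide. The column medians there were 0.0868, 0.329 and −0.0121 for the control arrays, 0.140, 0.161, −0.223 and 0.180 for the 48 h arrays and 0.0107, −0.164 and −0.129 for the 72 h arrays, all near 0 because most probes carried no signal.

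Each array holds 2421 probes that are not controls, 2125 of them for 723 human miRNAs and the others for 76 viral miRNAs, with 3 to 16 spots per probe and 1 to 4 probes per human miRNA. Spots marked as outliers were left out (655 to 825 of 12784 per array), no spot was saturated, and the processed intensity was averaged over the remaining spots of a probe. A probe counted as well above background on an array where at least 50% of its spots did. Each array was divided by the 75th percentile of the 178 probes well above background on all 10 arrays. Values under 0.0747, the median over arrays of the lowest scaled signal among probes well above background, were set to it, and log2 was taken. A miRNA was represented by its probe with the highest mean over all arrays. Among the changed miRNAs, the probes of 0, 1 and 0 had opposite signs at 48 h, at 72 h and between these times. The 141 human miRNAs well above background on at least 3 arrays, in whatever group, were tested. Background limits what dim probes can show: 48 of the 95 changes at 48 h, 44 of the 99 at 72 h and 37 of the 69 between these times were in miRNAs with a mean unscaled intensity under 30.

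The main model was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with version 1.17.8 of data.table to read the files), with 1 mean per group over all 10 arrays, 7 residual and 6.63 prior degrees of freedom, no covariate, two-sided tests and Benjamini-Hochberg adjustment within each comparison, with a threshold of 0.05 and no fold minimum. The contrasts were 48 h against control, 72 h against control, 72 h against 48 h, and the mean of both starved groups against control. Array brightness was compared with two-sided exact permutation tests. Where no array of a group had a probe well above background, "at least" folds set the other group's mean against the mean, per array of the dim group, of the higher of the array's lowest signal well above background and the probe's own signal. Of the changes past the threshold, 8 at 48 h, 13 at 72 h and 4 between these times were in miRNAs not well above background on any array of at least 1 of the groups compared, so their fitted size depends on the floor. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

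The text names, per comparison, the 12 largest rises and the 12 largest falls among miRNAs past the threshold whose groups do not overlap, and examples from 21 lists fixed before the data were examined. The lists are contractile smooth muscle, synthetic or proliferating smooth muscle, the miR-17-92 clusters, let-7, miR-29, miR-15/16, p53-induced, hypoxia-induced, miR-23/27/24, miR-30, the miR-99, miR-100 and miR-125 family, the miR-199 and miR-214 cluster, miR-181, the miR-130, miR-301, miR-148 and miR-152 families, the 14q32 imprinted cluster, markers of endothelium, blood cells, epithelium, cardiac and skeletal muscle, and liver and neurons, and GC-rich probes. Names outside this rule were chosen after their values were seen. The 11 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted within each comparison, with an estimated correlation and fry beside it. Camera compares a list with the other miRNAs, whereas fry asks whether the members move, on balance, in the same direction. Of 33 pairs of list and comparison, 7 passed with camera, 0 with an estimated correlation and 20 with fry.

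Alternatives fixed before the data were examined were scaling to the 75th percentile of all probes, to the median of detected probes or not at all, quantile normalization, a normexp background correction with an offset of 50, a floor of 0.5 times the main floor, the sum or mean log2 over a miRNA's probes, the total gene signal, the deposited value table, no filter on dim probes, detection on all arrays, only the groups compared, a trended and robust variance, array weights, the replicate number as a block, and each array left out in turn. The planned normexp correction uses the mean spot intensity, which the scanner files used here lack, so the median spot and background intensities took its place. Its offset is added to every spot before scaling, so the value of a dim probe under it depends much on array brightness. Scaling to 5 control probes, the slide column as a block and a limit of 30 on the mean unscaled intensity were added after seeing the data. These control probes were chosen by name and detection, and what they bind was not checked. Their unscaled log2 changes from control to 72 h ranged from −0.006 (mr_1) to 0.47 (hur_4). Slide 1 held the control arrays in its first row and the 48 h arrays in its second, and slide 2 the 72 h arrays, so a slide or scan block could not be fitted beside the groups.

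Names of miRNAs are those of the array's design, and some are old. A hairpin gene of the RefSeq table (GRCh38.p14) matched 131 of the 141 tested miRNAs by symbol, and the table was used only for which genes neighbour each other; no coordinates are given because the file headers name another build. The model was tested on simulated data with 40 changed miRNAs per run in 20 runs over 141 miRNAs. Of changes of 1 on the log2 scale 99.75% were recovered in each of the 3 comparisons, and of changes of 0.5, 93% at 48 h and 92.25% in both comparisons with 72 h, with 3.81%, 3.40% (72 h against control) and 3.13% (72 h against 48 h) of calls false. A shift of the 14q32 list at 48 h was recovered in 100% of 100 simulated runs with a mean of 0 other lists called. That 0 does not carry over to the real arrays, where 25 of 100 drawn splits gave as many list calls as the real groups.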

Results

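Mature microRNAs (miRNAs) were measured in primary human aortic smooth muscle cells on 10 Agilent miRNA arrays, a 1-colour platform on which Cy3-labelled small RNA binds probes that differ by the miRNA they capture. Control cells had been fed with 5% serum (3 arrays), and the starved cells had been without serum for 48 h (4 arrays) or 72 h (3 arrays). The labels describe starvation as a way to stop growth and to bring on genes of the differentiated smooth muscle state. The cells came from 2 lots, with 2 technical replicates per vial and time point, and the labels do not say which array is which. The p-values measure only the spread between these arrays, part of which may be technical. Of 723 human miRNAs on the array, 567 were well above background on none of the 10 arrays and 107 on all of them. The 141 that were so on at least 3 arrays were tested. The number of arrays limits the precision of every value below. Scaled log2 signals of arrays of the same group correlated across miRNAs at r of 0.993 to 0.998, and arrays of different groups at 0.946 to 0.983.

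The arrays differed in brightness before scaling. The 75th percentile of the intensity of 178 detected probes was 83.2 ± 16.0 in control cells (SD, n = 3), 159.9 ± 23.8 at 48 h (n = 4) and 115 ± 8.07 at 72 h (n = 3). The 48 h arrays were 1.92 times as bright as the control arrays (two-sided exact permutation p = 0.0571) and the 72 h arrays 1.38 times (exact p = 0.1, the smallest that 3 against 3 can give). The control probes were 1.34 times as bright at 48 h (exact p = 0.0857) and 1.23 times at 72 h (exact p = 0.1). All changes are given relative to each array's 75th percentile. With this scaling the median log2 fold change of the 141 miRNAs was −0.19 at 48 h, −0.24 at 72 h and 0.04 between 72 h and 48 h, and without scaling it was 0.70, 0.18 and −0.41. All 3 groups also differ by place on the slides, since control and 48 h arrays filled different rows of slide 1 and the 72 h arrays were alone on slide 2.

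**Figure D1:**
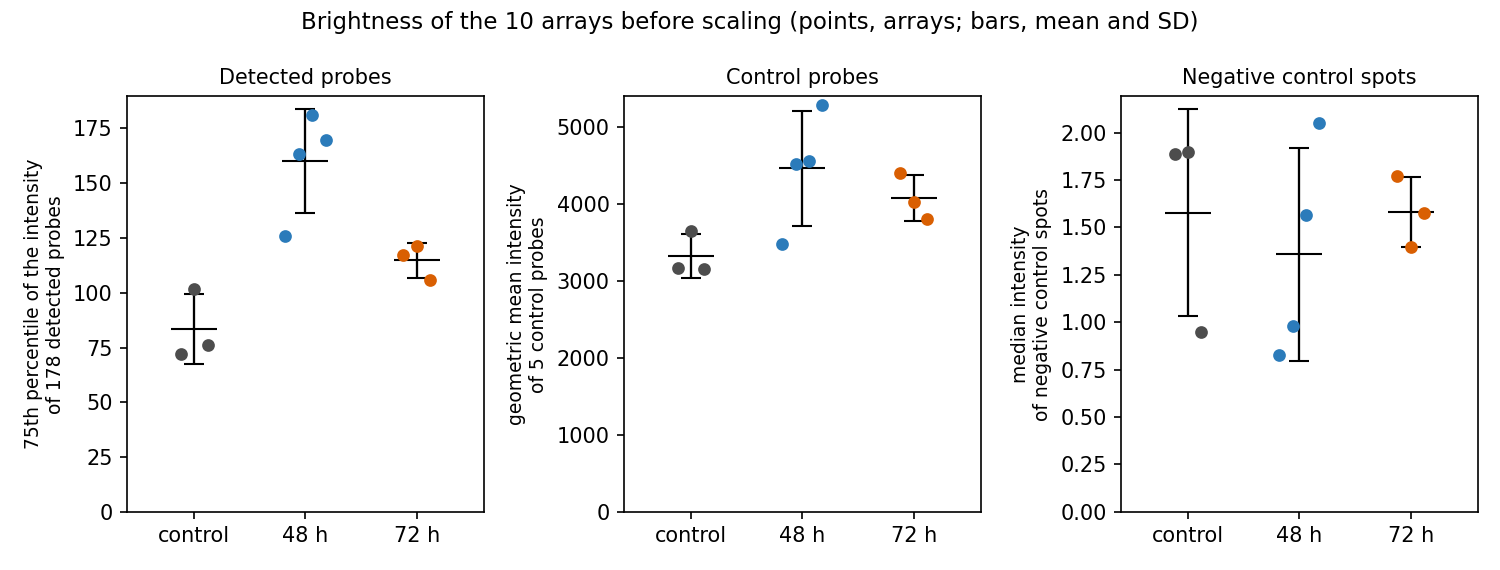
Intensity of each array before scaling, as the 75th percentile of 178 detected probes, the geometric mean of 5 control probes and the median of the negative control spots (intensity units; points are arrays, bars are mean and SD; 3 control, 4 48 h and 3 72 h arrays). The detected probes averaged 83.2 in control cells, 159.9 at 48 h and 115 at 72 h, while the negative control spots averaged 1.58, 1.36 and 1.58.

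After 48 h without serum, the smooth muscle miRNA miR-145 was higher and miR-221, which is known to promote smooth muscle proliferation, was lower. miR-145, which favours the contractile state, rose by 1.07 ± 0.09 on the log2 scale (SE; 2.10-fold; 4 against 3 arrays; limma adjusted p = 6.94e-07), though with a normexp background correction its change was −0.02. That correction adds an offset of 50 to every spot before scaling. Unscaled, miR-145 averaged 12.8 on control and 51.2 on 48 h arrays, so the corrected value depends much on array brightness. It cannot decide whether miR-145 rose, and this limit holds for other dim miRNAs given with this correction. miR-143, made from the same precursor transcript as miR-145, was well above background on 0 of 3 control arrays and 4 of 4 starved arrays. It passed the threshold as higher (adjusted p = 0.000510), but no size is given because control values lay at or near the floor. With the normexp correction the fitted change of miR-143 was −0.35, which has the same limit. Further rises were those of miR-26a (2.13-fold), miR-34a, a transcriptional target of p53 (1.77-fold), miR-146a, which is induced by NF-kB signalling (log2 0.77), miR-214 (1.56-fold) and miR-181a (1.37-fold). miR-221 fell by 0.91 on the log2 scale (SE 0.08; adjusted p = 1.16e-06), whereas its cluster partner miR-222 had a change of 0.14 that did not pass (adjusted p = 0.196). Without scaling, miR-221 had a change of 0.03.

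Of the 141 miRNAs, 26 rose and 69 fell at 48 h (limma, Benjamini-Hochberg adjusted p under 0.05), 9 of these 95 by more than 2-fold. The groups did not overlap for 95 of the 141 miRNAs, where chance gives 5.71% of miRNAs. These are not the same 95, since 25 of the rises and 62 of the falls were without overlap. The other rises among the 12 of largest size were those of miR-150* (2.40-fold), miR-939, miR-874 (1.73-fold), miR-1225-5p (1.69-fold) and miR-638 (1.48-fold). miR-939 was not well above background on any control array and was at least 1.76-fold higher at 48 h. With the normexp correction miR-939 and miR-1225-5p had changes of −0.14 and −0.08, with the limit given for miR-145. The largest falls were those of miR-758 (−1.14), miR-495 (−1.07), miR-410 (−1.06) and miR-494 (−1.05 ± 0.28), 4 miRNAs of the imprinted cluster at 14q32. They were followed by miR-33b* (−1.03), miR-886-3p (−0.95), let-7f-1* (−0.93), miR-766 (−0.89), miR-129-3p (−0.89), miR-933 (−0.86) and miR-1234 (−0.86). miR-129-3p was well above background on 2 of 3 control and 1 of 4 starved arrays. Without scaling, all 12 of the largest falls had changes between −0.20 (miR-758) and 0.09 (miR-1234). Those of miR-766 and miR-933 were 0.05 and 0.08. Some names are those of the array's design: miR-886 has since been described as a fragment of a vault RNA, miR-923 as a fragment of ribosomal RNA and miR-768 as derived from a small nucleolar RNA.

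Of the 18 tested members of the 14q32 imprinted cluster, a list fixed before the data were examined, 17 fell at 48 h (17 adjusted over the list alone). Their median log2 fold change of −0.55 turned to 0.17 when scaled to all probes and to 0.28 without scaling. The cluster was lower than the other miRNAs (limma camera adjusted p = 0.00204; adjusted p = 0.533 with an estimated correlation), and within slide 1 alone the adjusted p was 0.00122. Among the 74 miRNAs with a mean unscaled intensity of at least 30 the adjusted p was 0.0652. Of the miR-17-92 cluster and its paralogs, which MYC activates and which promote proliferation, 6 of 8 tested members fell (6 adjusted over the list alone), though their median of −0.43 turned to 0.37 when scaled to all probes, 0.47 without scaling and 0.08 with control probe scaling. Among them were miR-17 (−0.77), miR-92a (−0.67) and miR-20a (−0.57), and the list did not pass as a set (camera adjusted p = 0.129). In the cluster of miR-199 and miR-214, 3 of 4 tested members rose (3 adjusted over the list alone), with a positive median under all 7 scalings. These were miR-214 (0.64), miR-199a-5p (0.41) and miR-199b-3p (0.23), and the set missed the threshold (camera adjusted p = 0.0582). Both tested members of the contractile smooth muscle list passed as higher (2 adjusted over the list alone). The other 5 of its 7 miRNAs on the array, among them miR-1, miR-133a and miR-133b, were well above background on no array. The median of the 2 tested members was 0.81 and turned to −0.18 with the normexp correction, whose offset keeps it from deciding the direction of these 2 miRNAs. That median uses miR-143 at its fitted change, and with miR-143 at no change it would be 0.54. The list of the synthetic or proliferating state split, with miR-26a and miR-146a rising and miR-221, miR-31* (−0.69) and miR-24 (−0.25) falling among 9 tested (5 adjusted over the list alone). Its median was 0.03 (0.00 with miR-21*, not well above background on any control array, at no change), turning to just below 0 with the normexp correction. Camera placed it up and fry down, neither past the threshold (adjusted p = 0.497 and 0.547).

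Of 9 let-7 members, 1 rose at 48 h (let-7c, 0.30; 0 adjusted over the list alone; camera adjusted p = 0.119), and the family's median was positive under all scalings. The miR-29 family, which represses collagen genes, had 1 of 3 members up (miR-29c, 0.23) and 1 down (miR-29b, −0.30; 2 adjusted over the list alone; camera adjusted p = 0.893). Its median was −0.13 and turned to 0.72 when scaled to all probes, 0.82 without scaling and 0.41 with control probe scaling, and camera's direction was up. In the miR-15/16 family 1 of 5 fell (miR-15b, −0.28; 1 adjusted over the list alone; camera adjusted p = 0.926). The family's median was −0.15, turning to 0.70 when scaled to all probes, 0.80 without scaling and 0.38 with control probe scaling. miR-34a was the 1 tested member of the p53-induced list. miR-210, which hypoxia induces, rose by 0.31 (adjusted p = 0.0125), turning to −0.23 with the normexp correction, with the limit given for miR-145. Of markers of other cell types, none of 7 epithelial, 7 cardiac and skeletal muscle or 4 liver and neuron miRNAs was well above background on any array. Of 8 blood cell miRNAs, miR-155 alone was tested and fell (−0.63, turning to 0.22 scaled to all probes and 0.32 without scaling). Of 2 endothelial miRNAs, miR-126 alone was tested and had a change of −0.04 that did not pass (adjusted p = 0.701). Members not well above background in a group compared also weigh on these medians. With them at their lower bound, or at no change where there is none, the 14q32 median was −0.53 and 16 members with signal in both groups fell. The list of GC-rich probes was fixed as sensitive to RNA quality or hybridisation, but neither GC content nor this sensitivity was tested here. On it, 5 of 15 members rose and 8 fell, 3 and 7 of them with signal in both groups. Adjusted over the list alone, 13 passed. Camera placed the list up (adjusted p = 0.497), as did fry (adjusted p = 0.876). Its median was −0.19 (0.00 with such members at their bounds) and turned to 0.34 scaled to all probes, 0.44 without scaling and 0.09 with control probe scaling. Among its members are miR-150*, miR-939, miR-1225-5p, miR-638, miR-663, miR-766, miR-1234, miR-923 and miR-494, and miR-494 is also on the 14q32 list.

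The split between rises and falls at 48 h followed the scaling. It was 26 and 69 in the main setting, 35 and 58 with the median of detected probes, 36 and 56 with quantile normalization and 19 and 97 with the normexp correction. It was 75 and 15 with control probe scaling, 94 and 0 with all probes and 102 and 0 without scaling. The 26 rises were called in these last 3 as well, whereas 15 of the 69 falls were called with control probe scaling and 0 with the other 2. Both groups lay on slide 1, and within it 27 miRNAs rose and 71 fell. Each group filled a row of its own, so the row and the starvation cannot be told apart.

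**Figure D2:**
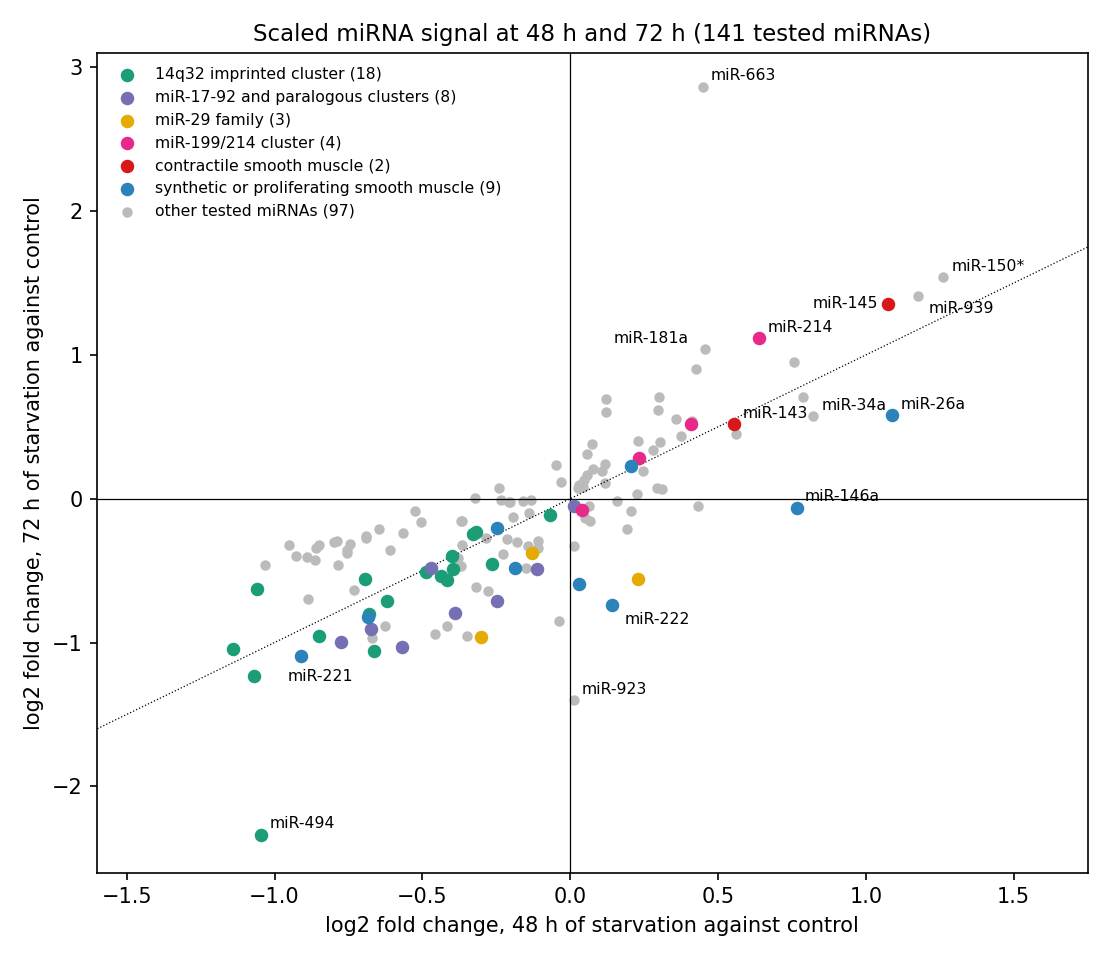
Log2 fold change of 141 miRNAs after 48 h (x axis) and 72 h (y axis) of serum starvation against the same 3 control arrays, with members of 6 lists in colour and the line of equal change dotted. The 14q32 cluster lies low on both axes (medians −0.55 and −0.56, which turn to 0.17 and 0.04 when scaled to all probes and at 48 h to 0.28 without scaling), and miR-663, miR-923 and miR-222 lie far from the dotted line.

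After 72 h without serum, miR-145 was 2.56-fold above the fed cells (log2 1.35 ± 0.09, SE; 3 against 3 arrays; limma adjusted p = 5.61e-08). miR-143 passed as higher (adjusted p = 0.00135), without a size because 0 of 3 control arrays were well above background. The median of the contractile list was 0.94, from 0.05 to 1.29 over the scalings (2 adjusted over the list alone), and 0.68 with miR-143 at no change. miR-221 was 2.13-fold lower and miR-222 was now lower as well (−0.74; adjusted p = 2.15e-05). miR-214 was 2.17-fold and miR-181a 2.05-fold higher. miR-494 showed the largest fall, 5.05-fold (−2.34 ± 0.30, limma adjusted p = 1.13e-05). Its 72 h arrays differed, with scaled signals of 0.308, 0.322 and 0.926, against 2.15 to 2.51 on the control arrays. The largest rise was that of miR-663, which was well above background on 0 of 3 control and 3 of 3 starved arrays and at least 4.53-fold higher (adjusted p = 3.03e-11).

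Of the 141 miRNAs, 32 rose and 67 fell at 72 h (limma), 13 of these 99 by more than 2-fold. The groups did not overlap for 99 of the 141 miRNAs, where chance gives 10% of miRNAs. Again these are not the same 99, since all 32 rises but only 64 of the falls were without overlap. The remaining rises among the 12 of largest size were those of miR-150* (2.91-fold), miR-939 (at least 2.07-fold), miR-1225-5p (1.93-fold), miR-140-5p (1.86-fold) and miR-140-3p (1.64-fold), the arms of 1 hairpin, miR-874 (1.63-fold), miR-768-3p (1.62-fold) and let-7b (1.53-fold). The remaining falls were those of miR-923 (2.64-fold), miR-495 (−1.23; well above background on 1 of 3 starved arrays), miR-376a (−1.06), miR-758 (−1.05; 2 of 3), miR-20a (−1.03), miR-17 (1.99-fold), miR-128 (−0.97; 2 of 3), miR-29b (−0.96), miR-409-3p (−0.96) and miR-224 (−0.95).

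In the 14q32 cluster 16 of 18 tested members fell at 72 h (16 adjusted over the list alone; 15 with signal in both groups), with a median of −0.56 that turned to 0.04 when scaled to all probes. Its camera adjusted p was 0.00217 (adjusted p = 0.273 with an estimated correlation, and 0.0620 among the 74 brighter miRNAs). In the miR-17-92 clusters 7 of 8 fell (7 adjusted over the list alone; 6 with signal in both groups), with medians from −0.75 to −0.06 over the scalings. miR-20a, miR-17 and miR-92a (−0.91) fell by the most, and the camera adjusted p was 0.0213 (adjusted p = 0.273 with an estimated correlation, and 0.0909 with control probe scaling). In the miR-199 and miR-214 cluster 3 of 4 rose (3 adjusted over the list alone), with medians from 0.34 to 1.09 over the scalings. Its camera adjusted p was 0.0403 (adjusted p = 0.273 with an estimated correlation), and the call was lost in 14 of 28 alternatives (adjusted p from 0.00718 to 0.290). Among these were the scalings to all probes (0.202), to the control probes (0.156) and to the median (0.0621), quantile normalization (0.0619) and no scaling (0.157). It was also lost without control array 1 (0.0813), 72 h array 1 (0.0501) or 72 h array 2 (0.0535).

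Of the list of the synthetic or proliferating state, 5 of the 8 members with signal fell and 2 rose at 72 h (8 adjusted over the list alone, with miR-21*; camera adjusted p = 0.331), with a median of −0.48 that turned to 0.21 when scaled to all probes. miR-21* passed as lower but was not well above background on any control or 72 h array, so it gives no measured change. With it at no change the median was −0.21. The falls were those of miR-221, miR-31* (−0.82), miR-222, miR-31 (−0.48) and miR-24 (−0.21), and the rises those of miR-26a (0.58) and miR-21 (0.23). All 3 tested miR-29 members fell (3 adjusted over the list alone), with a median of −0.56 that turned to 0.13 when scaled to all probes. The set did not pass (camera adjusted p = 0.240). In the miR-15/16 family 4 of 5 fell (4 adjusted over the list alone; camera adjusted p = 0.381), the median of −0.29 turning to 0.40 when scaled to all probes and 0.19 without scaling. Of 9 let-7 members 3 rose, let-7b, let-7c (0.40) and let-7e (0.34) (2 adjusted over the list alone; camera adjusted p = 0.241; positive medians under all scalings). miR-34a rose by 0.58, and miR-210 had a change of 0.07 that did not pass (adjusted p = 0.590). The markers miR-126 (−0.85) and miR-155 (−0.89) fell, with the same sign under all scalings. Of the GC-rich probe list 5 of 15 rose and 5 fell (3 and 5 with signal in both groups; 10 adjusted over the list alone). Camera did not pass (up, adjusted p = 0.241), whereas fry did (up, adjusted p = 0.0248). The list's median was −0.16, turning to 0.48 scaled to all probes, 0.27 without scaling and 0.01 with control probe scaling and with quantile normalization.

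The 32 rises and 67 falls at 72 h became 37 and 48 with the median of detected probes, 35 and 44 with quantile normalization and 18 and 87 with the normexp correction. They became 31 and 32 with control probe scaling, 73 and 4 with all probes and 51 and 14 without scaling. The 72 h arrays were alone on slide 2, so the slide, its scan and the 72 h of starvation cannot be told apart, in this comparison and in that with 48 h.

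**Figure D3:**
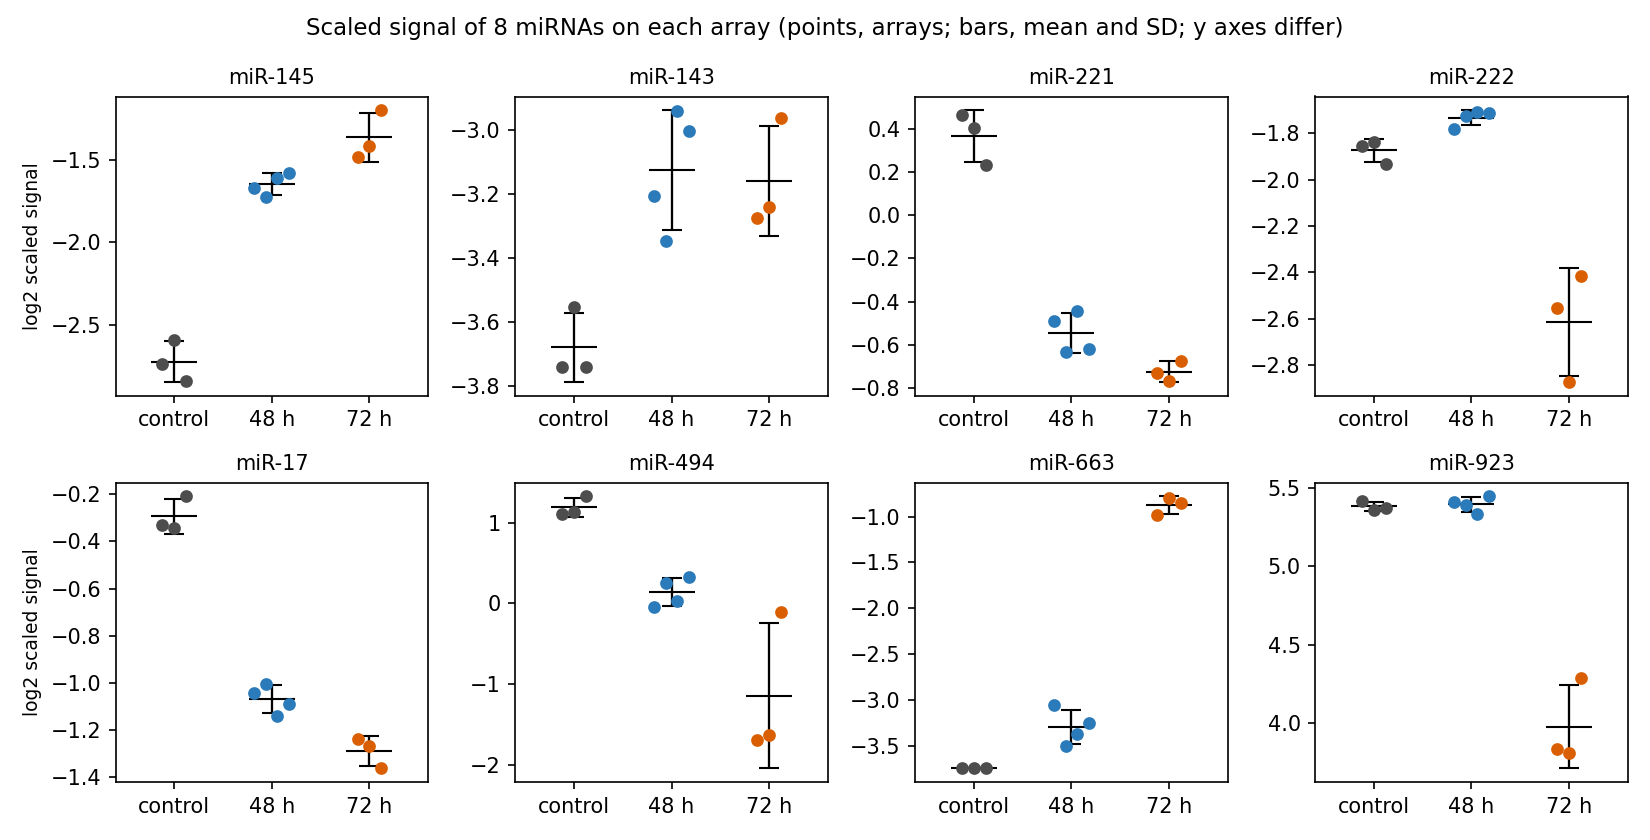
Log2 scaled signal of 8 miRNAs on each array (points; bars are mean and SD; 3 control, 4 48 h and 3 72 h arrays; y axes differ between panels). miR-145 lies above the control arrays at both times (log2 fold changes 1.07 and 1.35), miR-221 below (−0.91 and −1.09), and miR-222, miR-663 and miR-923 differ between 48 h and 72 h; the 3 control values of miR-663 are at the floor, and miR-143 was not well above background on any control array.

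Between 48 h and 72 h of starvation, miR-222 fell by 0.88 on the log2 scale (SE 0.10; 1.84-fold; 3 against 4 arrays; limma adjusted p = 8.28e-06), and miR-146a, which had been higher at 48 h, fell by 0.83 (adjusted p = 4.67e-06). The miR-29 family was lower at 72 h in all 3 tested members, miR-29c by 0.79, miR-29b by 0.66 and miR-29a by 0.25, with the same sign of the median under all scalings. Its camera adjusted p was 0.0257 (adjusted p = 0.476 with an estimated correlation). miR-145 was higher at 72 h than at 48 h by 0.28 (adjusted p = 0.0185) and miR-143 was not told apart (−0.03; adjusted p = 0.791). The contractile list's median of 0.12 (1 of 2 rose; 1 adjusted over the list alone) turned to −0.03 scaled to all probes, −0.34 without scaling and −0.23 with control probe scaling. miR-663 was 5.34-fold higher at 72 h and miR-923 2.66-fold lower.

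Between these times 36 miRNAs were higher and 33 lower at 72 h (limma), 3 of the 69 by more than 2-fold. The groups did not overlap for 73, where chance gives 5.71%. The rises after miR-663 were those of miR-886-3p (0.63), miR-181a (0.58), miR-768-3p (0.58), miR-33b* (0.57), let-7b* (0.53), let-7f-1* (0.53), miR-1234 (0.52), miR-149 (0.50), miR-296-5p (0.49), miR-766 (0.48) and miR-342-3p (0.48). The falls included miR-494 (−1.29), miR-126 (−0.81; well above background on 1 of 3 arrays at 72 h), miR-224 (−0.60), miR-26a (−0.51) and miR-26b (−0.48). For miR-494, 72 h array 3 (scaled signal 0.926) lay just under the lowest 48 h array (0.972). miR-21* and miR-218 were not well above background on any 72 h array and were at least 1.46-fold and 1.33-fold lower. With the normexp correction miR-126, miR-21*, miR-224 and miR-218 had changes of 0.06, 0.10, 0.00 and 0.11, which depend much on array brightness through its offset.

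As a set, the miR-17-92 clusters were lower at 72 h than at 48 h, with a median of −0.30 that turned to 0.02 with the normexp correction. Of 8 members 6 fell (6 adjusted over the list alone; camera adjusted p = 0.0163; adjusted p = 0.476 with an estimated correlation). The list of the synthetic or proliferating state was lower as well, with a negative median under all scalings (camera adjusted p = 0.0163; adjusted p = 0.448 with an estimated correlation). Of 9 members 5 fell, miR-222, miR-146a, miR-21*, miR-26a and miR-31 (5 adjusted over the list alone; 4 with signal at both times). Of 28 alternatives, 6 ended the call of the miR-17-92 clusters (highest adjusted p 0.370, with the normexp correction), 5 that of the synthetic list and 8 that of the miR-29 family (3 adjusted over the list alone). All 3 calls were lost without scaling (adjusted p = 0.105 for each) and with control probe scaling (adjusted p = 0.177, 0.0526 and 0.0677). Without 72 h array 3 the miR-17-92 clusters had an adjusted p of 0.0536 and the miR-29 family of 0.0570. In the 14q32 cluster 2 of 18 fell and 1 rose (3 adjusted over the list alone; camera adjusted p = 0.404), its median of −0.09 turning to 0.21 with the normexp correction. Of the GC-rich probe list 8 of 15 were higher and 2 lower at 72 h than at 48 h (10 adjusted over the list alone), with a median of 0.25 that turned to −0.19 without scaling and −0.08 with control probe scaling. Camera placed it up without passing (adjusted p = 0.247), whereas fry passed (up, adjusted p = 0.0307).

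The 36 rises and 33 falls became 45 and 24 with the median of detected probes and 66 and 12 with the normexp correction. They became 5 and 28 with all probes, 1 and 70 with control probe scaling and 1 and 82 without scaling. Arrays of different slides are compared here.

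Taking the mean of both starved groups against the fed cells, 31 miRNAs rose and 77 fell (limma), 8 of the 108 by more than 2-fold. The split was 40 and 59 with the median of detected probes, 40 and 54 with quantile normalization and 18 and 98 with the normexp correction. It was 53 and 26 with control probe scaling, 85 and 3 with all probes and 84 and 3 without scaling. The folds at 48 h and 72 h correlated across the 141 miRNAs at r = 0.75, where unchanged groups against the same 3 control arrays gave 0.53 in 1000 simulations. Their covariance was 0.237 against a simulated 0.00668, a difference of 0.230. The same sign was seen for 86.5% of miRNAs against a simulated 67.9%. At both times 21 miRNAs rose and 53 fell, where independent lists would share 5.90 and 32.8, 1 was called in opposite directions and 22 at neither time. The simulated values already hold the array noise of the shared controls, whereas the expectation from independent lists does not. The 3 control arrays are too few to be split, so part of the excess over independent lists may come from the shared controls. A shift common to all control arrays was not simulated.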

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

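The tests of dim falls, of GC-rich rises and of bright miRNAs between 72 h and 48 h were chosen after the result was seen; the test of the slide and the counts of other splits were fixed before.

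The change in miRNA signal differed between 72 h and 48 h for 26 of the 37 named miRNAs of the starved comparisons (limma test of the difference, log2, 72 h minus 48 h). Lower at 72 h were the ribosomal RNA fragment miR-923 (−1.412), miR-494 (−1.29), miR-146a (−0.827), miR-29b (−0.659), miR-224 (−0.601), miR-26a (−0.508), miR-20a (−0.461), miR-376a (−0.397), miR-128 (−0.295), miR-34a (−0.248) and miR-17 (−0.22). Higher were miR-145 (0.281), miR-150* (0.282), miR-140-3p (0.41), miR-410 (0.43), miR-933 (0.436), miR-140-5p (0.472), miR-214 (0.476), miR-766 (0.482), miR-1234 (0.516), let-7f-1* (0.527), miR-33b* (0.571), miR-768-3p (0.575), miR-181a (0.582), miR-886-3p (0.629) and miR-663 (2.418).

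The differences between 72 h and 48 h, 69 miRNAs in all, set arrays of different slides against each other. For the 32 of them with a mean unscaled intensity of at least 30, it was asked whether signal failed to follow array brightness on these arrays. Within groups it followed the brightness of the other detected probes with a median log2 slope of 1.07 (95% bootstrap interval over miRNAs 0.969 to 1.16). The prediction, a median slope under 0.5, was not met. The 72 h arrays were 0.718 times as bright as the 48 h arrays. Weak following would therefore give rises after scaling, and a fall would need a slope above 1. The median mixes rises and falls, so it settles neither direction, and this explanation stays open for single miRNAs. These miRNAs share the same arrays, so the interval leaves out the spread between arrays. Nor does the slope bear on the common level that each scaling sets, which stays open. The 36 rises and 33 falls became 1 and 82 without scaling and 1 and 70 with control probe scaling. A change of the cells between 48 h and 72 h stays open beside a difference between slides, which cannot be told apart from it because all 72 h arrays lay on a slide of their own. The real split of the 7 arrays called 69 miRNAs and the highest of the other 34 splits 42. This argues against a chance split only with arrays as independent units, and technical replicates that cannot be assigned may lie among them. The slide, which divides the arrays in the same way, is not excluded.

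Another pattern lies in the falls at 48 h: of 69, 44 had a mean unscaled intensity under 30, against 4 of 26 rises. Scaling that does not suit dim probes may have made them. Within groups their signal followed array brightness with a median slope of 0.819 (0.635 to 0.932, again over miRNAs that share the same arrays). The slope lies above the 0.5 that a strong form needs. Its interval reaches below the 0.75 that would exclude this explanation, which stays open. A loss of these miRNAs per amount of labelled RNA stays open too, since their median log2 change was 0.270 unscaled (0.160 to 0.484) and −0.142 scaled to the control probes (−0.222 to 0.0541), which differ in sign. The real split called 95 miRNAs at 48 h and the highest of the other 34 splits 65. With arrays as independent units a chance split is argued against. Unassigned technical replicates and the row on the slide are not excluded.

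The last pattern is the rise of 5 GC-rich probes at 72 h (miR-663, miR-150*, miR-939, miR-1225-5p and miR-638). Some probes for viral miRNAs, which these cells are not labelled as carrying, rose too. The probe for kshv-miR-K12-3 rose by 1.143 at 48 h and 1.48 at 72 h, and that for ebv-miR-BART13 by 0.353 and 0.598, while hsv1-miR-LAT had changes of −0.12 and −0.16 that did not pass; 72 of the 76 viral miRNAs were well above background on no array. These 5 were picked as risen after scaling to array brightness, so their passing is no test of brightness as the cause. Of the list, 6 members rose without scaling, and after scaling their median change was 0.997, with miR-663 and miR-939 (0 of 3 control arrays well above background) at their lower bounds. Scaling moved the median of all 141 miRNAs from 0.18 to −0.24, and 5 of the 6 still passed as higher, among them miR-150* (1.54, SE 0.102) and miR-1225-5p (0.948, SE 0.104), which had signal in both groups. miR-574-5p went from 0.347 to −0.131, as brightness would need. With so few members the 95% bootstrap interval of the median was 0.158 to 1.86, so brightness stays open as a cause of at least part of the list's rise. Binding of labelled RNA other than the named miRNA may raise both kinds of probe, but this stays open. Only 3 viral probes had signal on at least 3 arrays. Those for kshv-miR-K12-3 and ebv-miR-BART13 rose, that for hsv1-miR-LAT did not pass, and their median of 0.598 at 72 h is the value of a single probe. A true rise of the 5 miRNAs stays open as untested.

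Among the 4 arrays at 48 h, a single array stood apart for 4 of 41 named miRNAs tested, where chance gives about 1 in 20: miR-758 (gap over range 0.88), miR-128 (0.86), miR-29b (0.831) and miR-26b (0.935).

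For the other counts of changed miRNAs, the 72 h comparison with control has too few splits for a share under 0.05 (99 real, 0 the highest of the other 9). For the mean of both starved groups a chance split is argued against, again with arrays as independent units (108 real, 0 the highest of the other 99 drawn). For the 7 list calls chance was not excluded, since 25 of 100 drawn splits gave as many, with a highest of 10.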

How the results depend on the processing

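Control probe scaling, the slide column block and the limit of 30 on the mean unscaled intensity were chosen after the result was seen. The 72 pairs of a named miRNA and a comparison were picked from these data for large changes without overlap, which favours keeping them. Of these pairs, all kept direction and call with each array left out (720 of 720). Without scaling, with all probes or with control probes, 155 of 216 did so, 57 kept the direction without passing and 4 reversed; in the other settings these were 1070, 24 and 8 of 1102. Counts with each array left out ranged from 86 to 98 at 48 h, 86 to 102 at 72 h, 52 to 72 between these times, 97 to 110 for the mean of both and 5 to 8 for lists. Among the counts that moved were, at 72 h, 65 without scaling and 63 with control probe scaling. Between 72 h and 48 h they included 33 with all probes and 24 with no filter (723 miRNAs tested). With the limit of 30 (74 tested) they were 48 (23 up, 25 down), 55, 35 and 57 in the 4 comparisons. The splits given with each comparison above show further moves. The 7 list calls became 4 without scaling, 12 with normexp, 14 with no filter, 2 with control probe scaling, 2 with the limit of 30, 0 with an estimated correlation and 20 with fry. Reversed at 48 h with normexp were miR-939 (−0.137), miR-145 (−0.016), miR-1225-5p (−0.083) and miR-143 (−0.349), and without scaling miR-221 (0.034), miR-766 (0.045), miR-933 (0.082) and miR-1234 (0.086). Between 72 h and 48 h, normexp reversed miR-126 (0.062), miR-21* (0.103), miR-224 (0.001) and miR-218 (0.11). Through the offset, the normexp values of these miRNAs depend much on array brightness, so the normexp reversals do not decide the direction. Fewer miRNAs tested lowers the counts under the limit of 30; for the others the cause was not tested. The replicate block gave 94, 102, 63 and 106 miRNAs and 5 lists. The numbers do not pair the arrays, since 4 of 9 same-numbered pairs had r over 0.1 (−0.25 to 0.59) and 3 of 10 arrays correlated best with their own number. Control and 48 h arrays in the same slide column had r of 0.59, 0.59 and 0.22, and all 8 same-column pairs ranged from −0.25 to 0.59. With the slide column as a block, all 72 named pairs kept direction and call. Blocks for slide and scan date were not run, since they coincide with groups; the trended variance was not run for lists, and the groups-only fit not for the mean of both. Signal near background also limits what dim miRNAs can show.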

Other observations

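The test of all neighbouring pairs was chosen after the result was seen; the tests on pairs outside the lists and of different families were written before.

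In the paralogous miR-23/27/24 clusters the directions at 48 h depended on the scaling, and no test set the 2 clusters against each other. In the main scaling, from the cluster with the b members, miR-27b rose by 0.41 and miR-23b by 0.36, while miR-27a of the other cluster fell by 0.37 on the log2 scale, miR-23a had a change of −0.14 that did not pass, and miR-24, made by both, fell by 0.25 (4 adjusted over the list alone; camera adjusted p = 0.593). The list's median of −0.14 turned to 0.70 scaled to all probes, 0.80 without scaling, 0.39 with control probe scaling and 0.11 with normexp, and its mean was 0.00. All 5 rose with all probes and without scaling, and 0 fell with control probe scaling (3 rose) or with normexp (2 rose). At 72 h miR-23b (0.56) and miR-27b (0.54) rose and miR-24 (−0.21) fell (3 adjusted over the list alone; camera adjusted p = 0.275), the median of −0.10 turning positive under each other scaling, 0.04 to 0.59. Between the times 1 of 5 rose (0 adjusted over the list alone; camera adjusted p = 0.404).

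In the miR-30 family the guide strands miR-30a (0.25) and miR-30b (0.29) rose at 48 h, and miR-30a* (−0.53) and miR-30c (−0.24) fell (4 of 6 adjusted over the list alone; camera adjusted p = 0.497), with a median of 0.09 that turned to −0.45 with normexp. At 72 h 3 of 6 passed as higher (1, miR-30d, adjusted over the list alone; camera adjusted p = 0.180), the median of 0.14 turning to −0.19 with normexp. miR-30a rose by 0.20, and no size is given for miR-30d and miR-30e* because they were well above background on 0 of 3 control arrays. With both at no change the medians were 0.00 at 48 h and 0.04 at 72 h. Of the miR-99, miR-100 and miR-125 family 1 of 5 rose at 48 h, miR-125a-5p by 0.37 (1 adjusted over the list alone; camera adjusted p = 0.496), with a median of 0.03 that turned to −0.13 with normexp. At 72 h miR-125a-5p (0.43) and miR-125b (0.25) rose and miR-99b fell by 0.34 (3 adjusted over the list alone; camera adjusted p = 0.275), with a positive median under all scalings. Of 2 tested miR-181 members, miR-181a rose at both times and miR-181b had changes of −0.16 and −0.02 that did not pass. Of the families of miR-130, miR-301, miR-148 and miR-152, miR-130b fell at 48 h (−0.73) and 72 h (−0.63) and miR-130a at 48 h (−0.32), the median turning at 48 h to 0.32 with all probes, 0.42 without scaling and 0.01 with control probe scaling, and at 72 h to 0.38 and 0.16 with all probes and without scaling.

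miRNA genes that lie close together are often cut from a shared transcript, and such neighbours may change together under starvation. Over 76 pairs of tested miRNAs with hairpin genes within 10 kb of each other, the mean absolute difference of their 72 h log2 fold changes was 0.420, against 0.636 when folds were shuffled among miRNAs, and a share of 7e-04 of 10000 shuffles was as low. Leaving out pairs of the 14q32 and miR-17-92 lists, 33 pairs had a mean difference of 0.382 (share 0.0028), so the hypothesis does not rest on those lists alone. Neighbours are often of the same family, whose probes can bind each other's targets: for the 16 pairs outside both lists and of different families the mean difference was 0.437 (share 0.0778). The bound written for this last test, a share of 0.05 or more, was too strict to exclude the hypothesis, since 16 pairs leave a wide spread and the observed value lay under the shuffled mean of 0.636, so shared transcripts stay open for those pairs. Binding between family members was not separated from them in the pairs of the same family. Pairs that share a miRNA are not independent.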
